A study of Homo sapiens with 9 samples.

How the data were processed

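RNA was measured in 9 cultures of HEK293 cells, a human embryonic kidney line, after 24 h with nicotinamide (NAM), an amide form of niacin, at 0, 5, 10, 15 or 20 mM. Per the labels, batch 1 held 1 culture at each of the 5 concentrations, and batches 2 and 3 each held 1 culture at 0 mM and 1 at 5 mM. There were thus 3 arrays at 0 mM, 3 at 5 mM and 1 each at 10, 15 and 20 mM. NAM was added as a 50 mM stock in fresh medium, so that the stock made up 10% of the volume at 5 mM, 20% at 10 mM, 30% at 15 mM and 40% at 20 mM, while control cultures received 2 ml of fresh medium. No array had the same volume of medium without NAM at each dose, so dose and replaced medium rise together. Total RNA was labelled with biotin, and each sample was run on 1 Affymetrix human expression array.

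The deposited values are MAS5 signals, an intensity per probe set on a linear scale that the authors computed, without a stated software version. The table holds 54675 probe sets, of which 62 are controls, and every array has the same 2% trimmed mean of 500.1, so the values were used as deposited without further scaling. Detection calls and scanner files were not part of the table. For arrays the number of samples limits the precision, and single arrays at 10, 15 and 20 mM give no spread of their own.

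Signals under 1 were set to 1 and log2 values were taken. The 62 control probe sets were left out of tests. Probe sets were tested where their mean log2 signal over the arrays of a fit was at or above the median of all probe sets, which left 27307 in each fit. Gene names came from the platform's probe table, brought up to date through Entrez gene IDs: 41091 probe sets name 1 gene, 1801 name several and 11721 are not in the table. Of these IDs 41043 were found in the gene reference and 0 symbols changed. For gene lists each gene was represented by the probe set with the highest mean log2 signal over all 9 arrays among those that name a single gene, giving 19775 genes before the filter.

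Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend and Benjamini-Hochberg adjustment at 0.05, two-sided throughout. The comparison of 5 with 0 mM used 6 arrays. The dose trend used the 5 arrays of batch 1 with dose as a linear term, which leaves 3 residual degrees of freedom, and its changes are given as log2 over the range of 20 mM. Single doses were compared with 0 mM in batch 1 by counts at a 2-fold threshold without a test. Agreement between batches was measured as correlation across probe sets with no array on both sides. Gene lists, 33 in number, covered NAM metabolism and its enzymes, stress responses, cell cycle, chromatin, core metabolism, signalling and markers of other cell types. They were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Lists with under 5 tested members were described only. These choices, the lists, the alternatives for scaling, filter, offset, variance prior, fold threshold and left-out arrays, and the rule for naming genes were fixed before the data were examined. By that rule the text names, in each direction, the 10 genes past the adjusted threshold with the largest change and, for 5 over 0 mM, the same sign in every batch (filled up, where fewer pass, by the smallest unadjusted p), up to 4 members of each list described, and NAMPT, NNMT, SIRT1 and PARP1.

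The labels pair the samples by batch. Across probe sets, the deviations of the 0 and 5 mM arrays of a batch from their group means correlated at 0.386, 0.536 and 0.616 in batches 1, 2 and 3, against 0.0838 or less for arrays of different batches. Fits with batch as a replicate block are therefore given beside those without. Chosen only after the data had been seen were the fits with 1 probe set per gene for the dose trend and for the blocked comparison, the fit with the actin ratio as covariate, the block with an estimated correlation, the lists of HOX genes and retinoic acid targets with their estimated correlation and left-out arrays, the order of the doses in the strongest list, leaving arrays out of the 9-array fit, and leaving a batch out of the blocked fit.

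The fits were tested on simulated data with the spread of the real arrays, 10 runs per setting. Without a block, 0 of 200 probe sets changed by log2 1 were recovered and 34.8% of those changed by log2 2. With the block the recovery was 44.8% and 87.2%, for the trend in batch 1 it was 20.4% and 75.5%, and for the trend over 9 arrays 20.1% and 73.1%. At log2 1 the false share among the calls was 12.1%, 11.9% and 13.5% for these 3 fits, above the 5% aimed at, and at log2 2 it was 8.93%, 8.34% and 6.83%. With 1 probe set per gene the false share was 9.11% for the block, 9.20% for the trend in batch 1 and 5.38% over 9 arrays at log2 1, and with a spread drawn from the fitted prior 7.07%, 15.4% and 7.41%. With that drawn spread the probe-set fits recovered 11.6%, 0% and 2.71% of the changes of log2 1. In the unblocked fit only 0.391% to 0.69% of unchanged probe sets had an unadjusted p under 0.05. In the list test, run on a single simulated data set, 0 of 31 lists were called along the dose without a simulated change. The noise was drawn independently for each probe set. That test therefore cannot show how many false calls arise where the members of a list vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.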

Results

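Expression was profiled in HEK293 cells, a human embryonic kidney line, after 24 h with nicotinamide (NAM). Of the 9 arrays, 3 were at 0 mM, 3 at 5 mM and 1 each at 10, 15 and 20 mM. All 9 had the same trimmed mean signal of 500.1 and median signals between 100.4 and 113, and log2 signals correlated between arrays at 0.890 to 0.968. Values at 10, 15 and 20 mM have no replicates. Most markers of other cell types lay below the median probe set: 6 of 8 blood cell markers, 6 of 10 epithelial markers and 7 of 10 fibroblast markers.

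The first experiment of the study asked at which concentration most transcripts differ from 0 mM. In batch 1 the genes HOXB6, GAL, H2BC5 and JUND lay further from 0 mM at each higher dose, on 1 array per dose. HOXB6, a homeobox gene, stood at log2 ratios of -0.72, -1.43, -1.59 and -1.95 at 5, 10, 15 and 20 mM, GAL at -1.09, -1.22, -1.72 and -1.87, the histone gene H2BC5 at 0.53, 1.21, 1.43 and 1.55, and JUND at 1.05, 1.40, 1.71 and 1.77. Over all 27307 probe sets, 862 were at least 2-fold higher and 924 at least 2-fold lower at 5 mM, 914 and 1754 at 10 mM, 954 and 1174 at 15 mM, and 1049 and 1160 at 20 mM. The count was thus 1786 at 5 mM and largest at 10 mM, with 2668. The balance of higher and lower depended on the scaling: quantile normalization gave 1132 higher and 1041 lower at 15 mM and 1186 and 1111 at 20 mM, and median centring gave 1160 and 943, and 1209 and 991. Arrays at the same dose in different batches were 2-fold apart at 2379 to 6313 probe sets, so that none of the counts for a single dose but that at 10 mM exceeded the smallest of these. Such pairs also differ by batch, unlike the doses of batch 1, so they do not measure the spread within a batch. In batches 2 and 3 the counts for 5 over 0 mM were 1464 and 2263.

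A limma fit of dose as 5 groups over all 9 arrays, with batch as a replicate block and the lone arrays assumed to vary like the others, called 0 probe sets at 5 mM. It called 32 higher and 509 lower at 10 mM, 11 and 26 at 15 mM, and 10 and 43 at 20 mM. At 5 mM 1460 probe sets had an unadjusted p under 0.05, which is 5.35%, 550 of them higher and 910 lower. The 509 probe sets lower at 10 mM had a median log2 ratio of -1.91 at 10 mM, -0.06 at 15 mM and -0.17 at 20 mM.

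**Figure D1:**
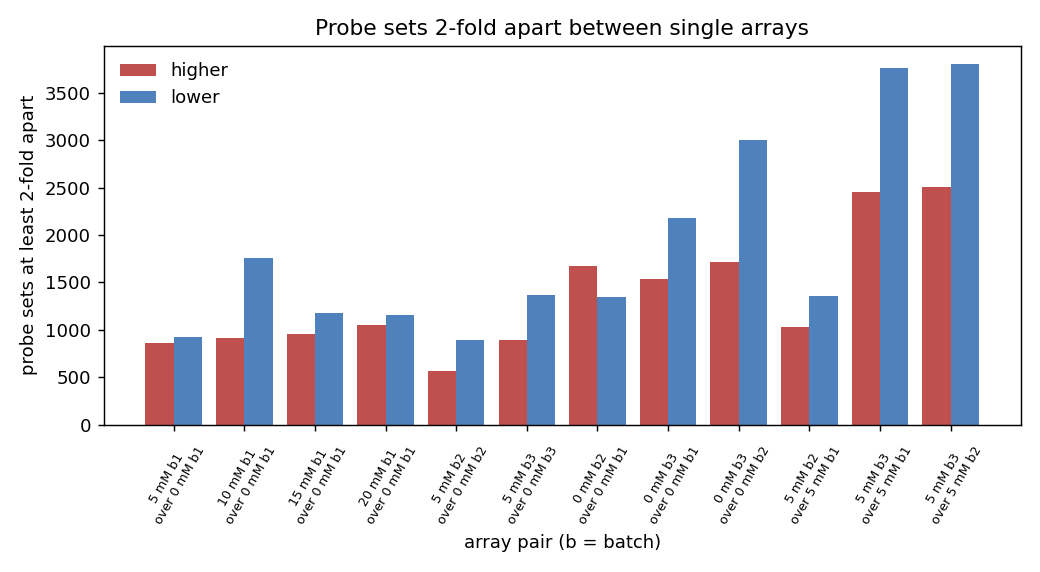
Number of probe sets at least 2-fold higher (red) or lower (blue) between 2 arrays, with the array pair on the horizontal axis (b stands for batch). The 10 mM array had 1754 probe sets lower than 0 mM, and arrays at the same dose in different batches were 2-fold apart at 2379 to 6313 probe sets.

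The second question was which transcripts differ between 5 and 0 mM in all 3 batches. CYP26A1, which encodes an enzyme that breaks down retinoic acid, fell with batch as a replicate block. Its mean signal was 790.4 ± 331 (SD, n = 3) at 0 mM and 185 ± 159 (SD, n = 3) at 5 mM, a log2 change of -2.35 (SE 0.26 with the block), and the 3 batches gave -2.75, -1.63 and -2.67. With 1 probe set per gene, NOG, which encodes the BMP antagonist noggin, also fell, with a log2 change of -1.03 and ratios of -1.40, -0.79 and -0.91. In the same fit C11orf96 rose by log2 1.17, with ratios of 1.104, 0.62 and 1.796.

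Without the block limma called 0 of 27307 probe sets, with the smallest adjusted p at 1.00, and 210 had an unadjusted p under 0.05, which is 0.769%, 61 higher and 149 lower. With batch as a replicate block it called 0 higher and 2 lower, CYP26A1 at an adjusted p of 0.0267 and a probe set without a gene in the probe table at 0.0366 with a log2 change of -2.12. In that fit 1485 probe sets had an unadjusted p under 0.05, which is 5.44%, near the 4.89% in simulated data without a change. With 1 probe set per gene, 0 of 11861 genes were called without the block and 108 had an unadjusted p under 0.05. With the block 1 was higher and 2 lower, at adjusted p values of 4.97e-04 for CYP26A1 and 0.0458 for both NOG and C11orf96. Without batch 1, 2 or 3 the blocked fit gave CYP26A1 log2 changes of -2.15, -2.71 and -2.19 (adjusted p 1.33e-11, 3.65e-08 and 1.39e-10). These fits have 1 residual degree of freedom and take the spread from the trend over all probe sets alone, and they called 116, 51 and 101 probe sets, more than the 2 called from all 3 batches. In simulated data without a change the blocked fit with 1 probe set per gene made 7 false calls, in 3 of 10 runs, and over all probe sets 4, in 2 of 10 runs.

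No other named gene passed in this comparison, so only values are given. Among those higher in 3 of 3 batches with the smallest unadjusted p, SUGP1 had a signal of 52.2 ± 12.7 (SD, n = 3) at 0 mM and 301 ± 103 (SD, n = 3) at 5 mM, a log2 change of 2.49. In batch 1, however, SUGP1 read 44.6 at 0 mM, 330.1 at 5 mM, 30.1 at 10 mM, 381 at 15 mM and 43.8 at 20 mM. The log2 changes were 1.70 for HCST, 1.60 for B3GAT1-DT, 1.91 for AKNA, 0.75 for TCAIM, 0.73 for CAMTA1, 1.02 for RBKS, 1.34 for KLC3, 0.63 for HADHA, which encodes a subunit of the mitochondrial fatty acid oxidation enzyme, and 1.21 for OGDH, a citric acid cycle enzyme. Among those lower in 3 of 3 batches, the PARP family gene TIPARP had -0.83, STEAP3 -1.15, SHISA2 -0.96, the ephrin gene EFNB3 -1.01, NR2F2-AS1 -1.18, SSH3 -1.77, GNB1L -1.05 and CKAP4 -0.58. MVK, which encodes mevalonate kinase, had -1.43 at this probe set, 0.85 at another and 0.28 at its brightest. Other probe sets differed in sign for more of these genes: the sign given here was that of 1 of 3 probe sets for OGDH, 1 of 2 for RBKS and for KLC3, 2 of 3 for SSH3, 3 of 4 for TCAIM and 4 of 6 for CAMTA1.

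**Figure D2:**
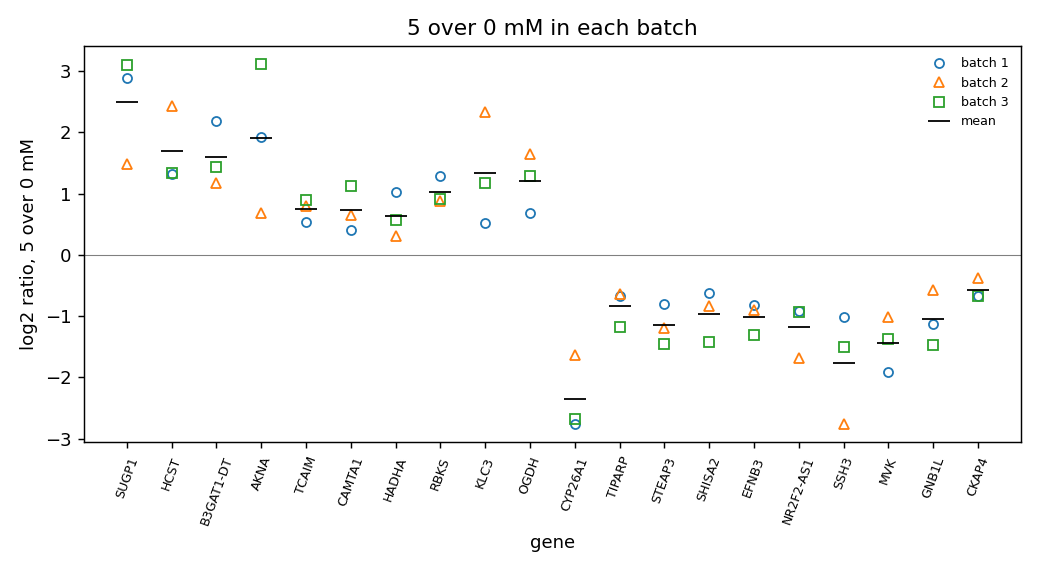
Log2 ratio of 5 over 0 mM (vertical axis) for the 20 genes named by rule in this comparison (horizontal axis), 1 symbol per batch, with the mean as a bar. CYP26A1 lies between -2.75 and -1.63 in the 3 batches.

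17 probe sets were at least 2-fold apart in the same direction in all 3 batches, 4 higher and 13 lower. With the sign of 1 batch turned the same count was 8, 9 and 8. The 17 hold SUGP1, HCST and B3GAT1-DT among the higher, and CYP26A1, MVK, SSH3, BCL6B, SPDEF, PLEKHG2, GPR161 and ING5 among the lower, the last 5 named after their values were seen.

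Replication-dependent histone genes were the 1 list of 31 tested that was called between 5 and 0 mM, with a mean log2 shift of 0.40 and 8 of 8 members higher. Camera gave an adjusted p of 0.00506, the adjusted p was 0.977 with an estimated correlation, and fry gave 0.984. Of its 8 members 0 passed over all genes tested and 0 passed adjusted over the list alone. H2BC21 had a log2 change of 0.76 (SE 0.42), H1-2, a linker histone, 0.71 (SE 0.42), H2BC5 0.55 (SE 0.37) and H2AC6 0.52 (SE 0.40). With batch as a replicate block camera gave 4.05e-05, and with an estimated correlation beside the block the adjusted p was 0.940. The call was lost without the 0 mM array of batch 2 (mean 0.21, adjusted p 0.855), without the 5 mM array of batch 3 (mean 0.26, adjusted p 0.264) and without the filter on dim probe sets (mean 0.29, adjusted p 0.265). The fits with an array left out had no block, so batch was unbalanced between 0 and 5 mM.

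Genes that handle NAM were not called. NAMPT, the rate-limiting enzyme of NAD salvage from NAM, had a signal of 3431 ± 1380 (SD, n = 3) at 0 mM and 3402 ± 1642 (SD, n = 3) at 5 mM, a log2 change of -0.05 (SE 0.39) that reads 0.0027 after median centring. SIRT1, a deacetylase inhibited by NAM, had -0.04 (SE 0.22), with 0.01 after median centring, and PARP1, which uses NAD in DNA repair, had 0.06 (SE 0.18), with -0.0044 after quantile normalization. NNMT, which methylates NAM, lay below the filter, at the 34.5 percentile of mean signal. The NAD synthesis list had a mean of -0.04 (adjusted p 0.821), the sirtuins -0.01 (0.893) and the PARP family -0.05 (0.821).

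The last comparison asked which transcripts follow the dose over 0, 5, 10, 15 and 20 mM in batch 1. Of the HOX genes, which set positional identity in the embryo, 3 fell with the dose over all genes tested: HOXB6 went from a signal of 1685 at 0 mM to 436 at 20 mM, and HOXB6, HOXD10 and HOXB3 had log2 changes over 20 mM of -1.91 (SE 0.26), -1.88 (SE 0.28) and -1.49 (SE 0.27). The homeobox genes DLX1 and DLX2 fell by 1.57 and 1.23 on the log2 scale, and GAL, the gene of the neuropeptide galanin, fell by 1.75. The AP-1 genes JUN and JUND rose by 1.24 and 1.68, the histone genes H2BC5 and H2AC6 by 1.60 and 1.79, and the tubulin genes TUBB2B and TUBA1A by 1.11 and 0.91. These verbs rest on the limma fit with 1 probe set per gene, in which 46 of 11871 genes passed, 27 rising and 19 falling, while the fit over all probe sets called 0.

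In that fit all 46 adjusted p values lay between 0.0342 and 0.0494. Of the genes given here HOXD10, HOXB3, DLX2, JUND, H2AC6, TUBA1A, RHOB, EPHX1, TRIP6, ZHX2, ALDH1A2, VARS1 and HMOX1 were chosen after their values were seen. Also rising were C11orf96 (2.24), ITPR1 (2.14), AAMDC (1.21), PHF20 (1.06), TSPAN13 (0.84), RHOB (1.42), which encodes a small GTPase, and EPHX1 (1.41), an epoxide hydrolase. Also falling were IRAK1 (-0.996), a kinase of Toll-like receptor signalling, SELENOH (-0.95), CELF2 (-1.17), an RNA-binding protein, TRIP6 (-1.73), ZHX2 (-2.38), ALDH1A2 (-1.17), which makes retinoic acid, VARS1 (-1.82), a tRNA synthetase, and HMOX1 (-1.52), the inducible heme oxygenase. Of the 27 rising genes 26 were above 0 mM at all 4 doses and 15 were above it at 5 mM in both batches 2 and 3. Of the 19 falling genes 18 were below 0 mM at all 4 doses and 13 were below it at 5 mM in both other batches. HMOX1 stood at 0.12 and 0.77 in batches 2 and 3, and ITPR1 at 0.37 and -1.01.

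Over all 27307 probe sets the trend in batch 1 called 0 rising and 0 falling, with the smallest adjusted p at 0.178, while 3176 had an unadjusted p under 0.05, which is 11.6%, 1582 rising and 1594 falling. With all 9 arrays and batch as a replicate block 5 rose and 10 fell, and with 1 probe set per gene in that fit 76 genes rose and 102 fell of 11850, 41 of them among the 46. Called among probe sets were HOXD10 (-2.68 and -1.87), HOXB6 (-1.98), TRIP6 (-1.79), GAL (-1.76), DFFA (-1.71), HNRNPD (-1.63), CELF2 (-1.17), TUBB2B (1.09), H2BC5 (1.66) and JUND (1.67), with adjusted p values from 0.0381 to 0.0495. Of the 3 probe sets of DFFA only 1 fell along the dose. HOXB9, HOXC9, HOXD11, HOXC10, HOXC6, HOXB2 and HOXB8 were among the 102 falling genes. The calls depend on single arrays: with 1 probe set per gene 0 of the 46 genes were called without the array at 0, 5, 15 or 20 mM, and 305 rising and 282 falling, with all 46 among them, were called without that at 10 mM. Over 9 arrays the 178 genes became 0 without the 0 mM array of batch 1, 52 without 5 mM, 362 without 10 mM, 27 without 15 mM and 44 without 20 mM of that batch, 23 without either array of batch 2, and 293 and 290 without the 0 and 5 mM arrays of batch 3.

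DTNA (-1.93), RPL31 (0.98), EPPK1 (1.66, and 1.69 at its brighter probe set) and ALDOA (-0.78) complete the genes named by rule. Of these DTNA and RPL31 did not pass in any of these fits. Their other probe sets had changes of 0.07 and 0.04 for DTNA and of 0.08 and -0.08 for RPL31. SIRT1 had a log2 change over 20 mM of 0.48 (unadjusted p 0.0251, adjusted p 0.349), NAMPT -0.22 (0.247 and 0.694) and PARP1 -0.15 (0.369 and 0.780).

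**Figure D3:**
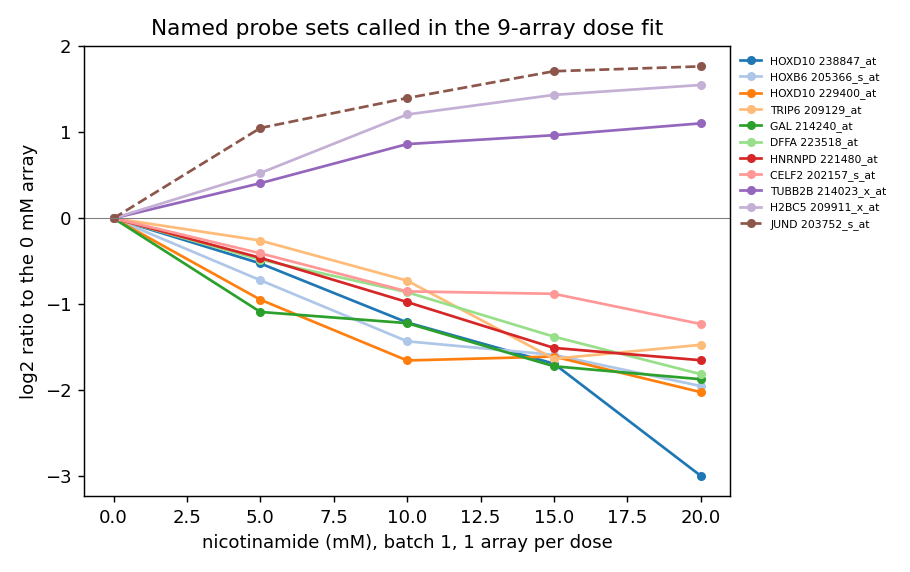
Log2 ratio to the 0 mM array of batch 1 (vertical axis) against NAM in mM (horizontal axis) for the named probe sets called in the 9-array dose fit, 1 array per dose. At 20 mM HOXD10 stands at -2.99 and -2.02 and JUND at 1.77.

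By lists, the replication-dependent histones rose along the dose, with a mean log2 change over 20 mM of 1.07 and 9 of 9 members rising. Camera gave an adjusted p of 1.76e-07, and the adjusted p was 0.451 with an estimated correlation. Fry called 0 lists along the dose, with adjusted p values of 0.0804 for the histones and for the immediate early genes. Without the filter on dim probe sets the histone mean was 0.64 (adjusted p 1.16e-05). H2BC5 and H2AC6 passed over all genes tested, and 6 passed adjusted over the list alone, with H2BC12 at 0.65 and H1-2 at 1.00 among those that did not pass over all genes. The mean over the 9 members was 0.13, 0.75, 0.80 and 1.01 at 5, 10, 15 and 20 mM in batch 1, and 0.15 and 0.65 at 5 mM in batches 2 and 3. The immediate early genes rose with a mean of 0.60, 9 of 10 members rising (adjusted p 2.36e-04, and adjusted p = 0.451 with an estimated correlation). Of them JUN and JUND passed over all genes and 5 passed adjusted over the list alone, and DUSP1 had 1.04 and MCL1 0.48. At 5 mM their mean was 0.24 in batch 1, 0.11 in batch 2 and -0.02 in batch 3, and with the mean of all probe sets per gene the mean along the dose was 0.39, with the call kept.

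The DNA replication list fell with a mean of -0.25, 30 of 37 members falling (adjusted p 6.23e-04, and adjusted p = 0.457 with an estimated correlation). With median centring the mean was -0.17, 27 members falling (adjusted p 0.00656). Over all genes 0 passed and 4 passed adjusted over the list alone, with CDC45 at -0.80, the helicase subunits MCM2 and MCM5 at -0.63 and -0.64, and UHRF1 at -0.59. At 5 mM the mean was -0.08 in batch 1, 0.05 in batch 2, where 23 of 37 members were higher, and -0.15 in batch 3. Glycolysis genes fell with a mean of -0.22, 16 of 18 members falling (adjusted p 5.00e-04, and adjusted p = 0.585 with an estimated correlation), ALDOA at -0.78, GPI at -0.89, PGAM1 at -0.32 and TPI1 at -0.38. Of these ALDOA passed over all genes and 4 members adjusted over the list alone. The glycolysis mean in batch 1 was 0.08, 0.13, -0.15 and -0.16 at 5, 10, 15 and 20 mM, it was -0.0053 and 0.15 at 5 mM in batches 2 and 3, and without the 0 mM array the mean change was -0.39. It was smaller with median centring (-0.13, 14 of 18 falling) and larger among the brightest 30% of probe sets (-0.35), with the call kept in each. Fry gave adjusted p values of 0.114 for DNA replication and 0.216 for glycolysis.

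The methionine cycle list fell with a mean of -0.29, 13 of 15 members falling (adjusted p 0.0231, and adjusted p = 0.451 with an estimated correlation). Adjusted over the list alone 3 fell and 1 rose, and 0 passed over all genes, with CBS at -1.01, MTHFD1 at -0.43, the spermidine synthase gene SRM at -0.66 and CTH at 0.59. The methionine cycle call was lost without the 20 mM array (adjusted p 0.05504), with median centring (mean -0.20, adjusted p 0.0573) and with the mean of all probe sets per gene (mean -0.14, adjusted p 0.0961). At 5 mM its mean was -0.06, 0.0019 and -0.14 in batches 1, 2 and 3. The heat shock list fell with a mean of -0.27, 10 of 14 members falling (adjusted p 0.0263, and adjusted p = 0.451 with an estimated correlation). Here 6 fell and 1 rose adjusted over the list alone and 0 passed over all genes, with HSPH1 at -0.57, the collagen chaperone SERPINH1 at -1.58, STIP1 at -0.76 and HSPA4L at 0.52. The heat shock call was lost without the 0 mM array (0.0598), without the 20 mM array (0.0633), with all 9 arrays and the block (0.141), with median centring (0.0928) and with the mean of all probe sets per gene (0.0790). At 5 mM the heat shock mean was -0.05, 0.0050 and 0.06 in batches 1, 2 and 3, with 8 of 14 members higher in each. FOXO targets rose with a mean of 0.28, 11 of 17 members rising (adjusted p 0.0375, and adjusted p = 0.451 with an estimated correlation), with 4 passing adjusted over the list alone and 0 over all genes: SESN3 had 0.96, SOD2 0.62, BCL6 1.27 and RBL2 0.57. The FOXO call was lost without the 0, 10 or 20 mM array (0.105, 0.0521 and 0.207), with all 9 arrays and the block (0.2004), among the brightest 30% of probe sets (0.1315) and with median centring (0.0501). At 5 mM the mean was 0.20 in batch 1 and -0.11 and -0.24 in batches 2 and 3. Fry gave adjusted p values of 0.0971 for the methionine cycle, 0.0685 for heat shock and 0.134 for FOXO targets.

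The HOX list was chosen after HOX genes had been seen among the top genes, so its count is not independent evidence of its direction. Of 23 members 22 fell along the dose with a mean of -1.09, 3 passed over all genes and 14 adjusted over the list alone. Camera over this list and that of the retinoic acid targets gave an adjusted p of 1.12e-12, and the adjusted p was 0.0757 with an estimated correlation. Beside those above, HOXB9 had -1.60, HOXC9 -1.66, HOXD11 -1.58 and HOXC10 -1.45, while HOXB13 had 0.64, all chosen after their values were seen. The mean was -0.20, -0.85, -0.96 and -0.98 at 5, 10, 15 and 20 mM in batch 1, and -0.41 and -0.31 at 5 mM in batches 2 and 3. For 5 over 0 mM in all 3 batches the HOX mean was -0.35, with 22 of 24 members lower and 0 passing over all genes (adjusted p 4.04e-09, and 0.0172 with an estimated correlation). That second value was 0.0695 without the 5 mM array of batch 3, in a fit without the block. Adjusted p values for HOX genes cover only this list and the retinoic acid targets. They are therefore not comparable with those over the lists fixed beforehand. Unadjusted camera p values with an estimated correlation were 0.0464 for HOX genes and 0.0383 for histones along the dose. At 5 mM they were 0.00858 and 0.0935.

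**Figure D4:**
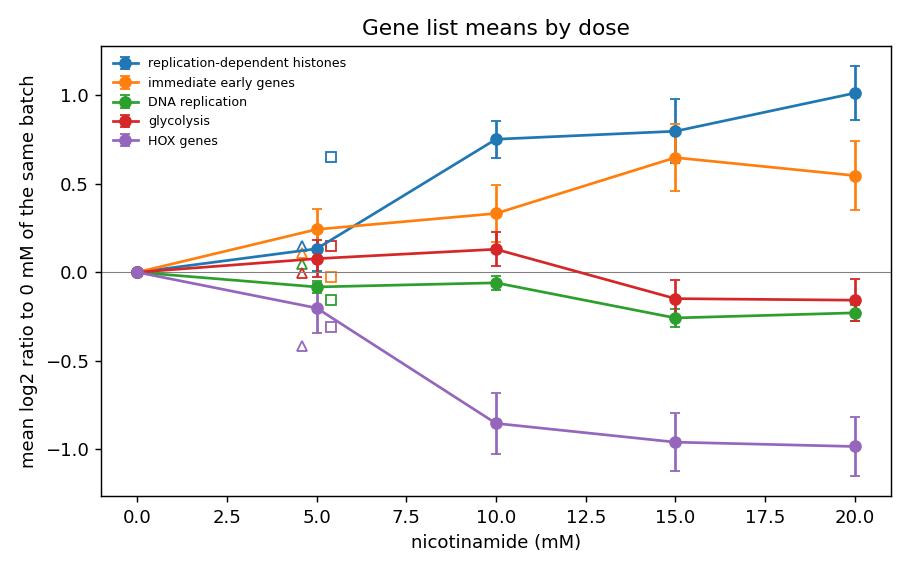
Mean log2 ratio to 0 mM of the same batch over the members of 5 gene lists (vertical axis) against NAM in mM (horizontal axis). Filled points with SE over members are batch 1, and open triangles and squares are batches 2 and 3 at 5 mM. The histone mean reaches 1.01 and the HOX mean -0.98 at 20 mM.

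Changes at each dose in batch 1 were compared across probe sets with the mean change at 5 mM in batches 2 and 3. Genes are not independent replicates, so only the size is given. Pearson's r was 0.0452 for 5 mM, 0.140 for 10 mM, 0.102 for 15 mM and 0.117 for 20 mM, and Spearman's rho was 0.0296, 0.192, 0.118 and 0.136. Among the brightest 30% of probe sets r was 0.0270, 0.274, 0.181 and 0.204. Of the 200 probe sets with the largest mean change at 5 mM in batches 2 and 3, 115 had the same sign at 5 mM in batch 1.

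The 3'/5' signal ratio of beta-actin, a sign of RNA quality, was 2.72 at 0 mM, 4.94 at 5 mM, 2.94 at 10 mM, 3.43 at 15 mM and 3.30 at 20 mM in batch 1. In batch 2 it was 4.46 at 0 mM and 4.10 at 5 mM, and in batch 3 1.85 and 1.90. The 5 mM array of batch 1 thus had the highest ratio of all 9, while within batches the log2 ratio correlated with dose at -0.00433.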

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

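Chosen only after the result was seen were the tests against batch 1 alone, against replaced medium, of the order of the doses in HOX genes not seen first and of that order in the strongest list, and also the actin covariate, the fits with 1 probe set per gene and the HOX list itself.

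Control probe sets outside the comparisons read above every 0 mM array in 5 cases. The 3'/5' ratio of beta-actin was 4.94 on the 5 mM array of batch 1, against 4.46 on the highest 0 mM array. The ratio of GAPDH was 1.165 on the 5 mM array of batch 1, 1.163 on the 15 mM array and 1.18 on the 5 mM array of batch 2, against 1.15. The ratio of the thr spike was 3.70 on the 5 mM array of batch 2, against 3.50.

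The first pattern is the rise of histone genes with the dose. A chance order of the doses was unlikely but not excluded. Of 60 orders of the 5 doses 1, the real one, gave a mean change as large (1.07, highest other 1.06), a narrow margin. As this list was the strongest of those tested, the strongest list of each order was compared too. There 2 of 60 orders gave a camera p as small, the other order a smaller one (minus log10 p 8.23, highest other 8.74). The actin 3'/5' ratio as covariate left 99.92% of the change over 9 arrays, but this test is void, since the ratio hardly follows dose within batches (r -0.00433) and moved no gene by more than 0.0183. In batches 2 and 3 the list stood at 0.1496 (SE 0.27) and 0.65 (SE 0.12) at 5 mM, and as the first lies within its SE of 0, which the bound written for that test had left out, a rise in batch 1 alone stays open. Replaced medium, 40% of the volume at 20 mM, cannot be told apart from NAM. No array had the same volume of medium without NAM at each dose, so that a response to NAM may be 1 of several sources.

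The second pattern is the fall of HOX genes with the dose. Picking of the genes for the list was tested on the 18 HOX genes not seen first. Their mean change was -0.9173 (SE 0.16), 17 of them falling, so the fall was not confined to the genes seen first. They share arrays and gene family with those genes, so the test cannot decide whether picking added to the fall. Over the whole list 1 of 60 orders gave a change as large (1.09, highest other 1.08), and in the genes not seen first 2 of 60 did, the other order being larger (0.94 against 0.917), but both tests use the arrays and the gene family that prompted the list, so a chance order stays open. The actin ratio left 99.98% of the change, in the same void test. At 5 mM batches 2 and 3 gave -0.41 (SE 0.08) and -0.3091 (SE 0.17), both lower than batch 1 (-0.20), with 4 and 7 of 23 members higher. The second lies within 2 SE of 0, short of the bound written for that test. A fall in batch 1 alone thus stays open by that bound, though the mean lay below 0 mM in both other batches. Each SE is over members of 1 pair of arrays, so it does not measure the spread between cultures. Higher doses were run in batch 1 only. The replaced medium (40% at 20 mM) cannot be told apart from NAM, which may be the source.

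The third pattern is the larger number of lower probe sets on the 10 mM array. Scaling was excluded, since after quantile normalization the count was still 1.377 times the highest of the other doses. Dim probe sets were excluded as well, with 2.648 times among the brightest 30%. As to a response that later doses share, only 3.12% of the median log2 ratio of the 509 probe sets called lower at 10 mM was left at 15 mM. These probe sets were chosen for low values on the 10 mM array itself. The test therefore covers them alone, and a shared response among the other lower probe sets stays open. What sets this single array apart, a technical fault or a response at 10 mM only, was not tested, and no replicate exists.

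Other splits and orders of the arrays were counted for each fit. For 5 against 0 mM without a block, 10 of 10 splits gave as many calls (real 0, highest other 0), and these splits are too few for a share under 0.05. With the block 4 splits part the batch pairs, also too few, and 1 gave as many calls, over probe sets (real 2, highest other 0) and with 1 probe set per gene (real 3, highest other 0). The histone shift at 5 mM (real 0.40, highest other 0.633) was reached by 3 of 10 splits, again too few. For the trend in batch 1 only the real order of 60 gave as many probe sets at an unadjusted p under 0.05, by a narrow margin (real 3176, highest other 2987). The same held for calls with 1 probe set per gene (real 46, highest other 1), a fit chosen after the data were seen. As 1 of 60 is the smallest share possible, a chance order is unlikely here but not excluded. Over 9 arrays a chance order is unlikely as well. Only 1 of 100 drawn orders, the real one, gave as many probe sets (real 15, highest other 1) or genes (real 178, highest other 23).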

How the results depend on the processing

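Chosen only after the data had been seen were the fits with the block or the dose trend and 1 probe set per gene, the block with an estimated correlation, the actin covariate, the left-out arrays of the 9-array fit and the block with a batch left out. The number of calls depends on the features tested, on the block and on single arrays, and the cause was not tested for any of these dependences. A count was labelled the same if it changed by no more than a set factor. Thus 1754 lower probe sets at 10 mM and 1425 with median centring were labelled the same. For list shifts and named genes the label means an unchanged sign and call, whatever the size. By these labels, of the values that answer a comparison 126 stayed the same, 42 were weaker, 47 stronger and 12 moved. Of the list shifts 696 stayed the same, 28 were weaker, 28 stronger and 7 reversed, and 121 shifts that were not called moved or changed sign. Of the named genes 646 stayed the same, 77 were stronger, and 10 values that were not called changed sign. Median signals lay -0.173 (log2) from 0 mM on the 5 mM array of batch 2 and -0.109 on the 10 mM array, which median centring removes.

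For 5 against 0 mM the block gave 2 lower probe sets, and with 1 probe set per gene 1 higher and 2 lower. The block without batch 1, 2 or 3 gave 33, 15 and 40 higher and 83, 36 and 61 lower, with 1 residual degree of freedom and the spread taken from the trend over all probe sets. For the dose trend 27 rose and 19 fell with 1 probe set per gene in batch 1, 5 and 10 with all 9 arrays and the block, and 76 and 102 with both. With the actin covariate over 9 arrays 2 fell. Leaving out an array of batch 1 gave 0 to 121 rising and 0 to 106 falling probe sets, the highest without 10 mM. The 15 calls over 9 arrays became 0 without the 5 mM array of batch 2, and without 0, 5, 15 or 20 mM of batch 1, 2 without 0 mM of batch 2, 34 without either array of batch 3, and 233 without 10 mM.

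Probe sets 2-fold one way in all batches, 17 in number, were 944 without a filter, 1 among the brightest 30%, 7 with an offset of 32, 4 with 1 probe set per gene, and 109 to 155 with a batch left out, where fewer conditions have to be met.

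Probe sets higher and lower at 5, 10, 15 and 20 mM in batch 1 moved with the filter and the threshold. Without a filter they were 8492 and 7579, 7576 and 9454, 7655 and 8615, and 8032 and 8436. Among the brightest 30% they were 73 and 111, 161 and 511, 166 and 177, and 196 and 193. At 1.5-fold they were 2612 and 2706, 2788 and 4010, 2854 and 3493, and 3071 and 3445. At 3-fold they were 267 and 261, 269 and 628, 279 and 267, and 283 and 316. By limma on all 9 arrays with the block they were 0 and 0, 32 and 509, 11 and 26, and 10 and 43. With an offset of 32 they were 523 higher at 5 mM, 594 higher at 10 mM, 623 and 703 at 15 mM, and 672 and 764 at 20 mM. The largest count of lower probe sets was at 10 mM in each of these settings that gives all 4 doses. Quantile normalization and median centring kept it at 10 mM (1530 and 1425) and turned the balance at 15 and 20 mM to more higher than lower.

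The correlation of batch 1 with the other batches at 5, 10, 15 and 20 mM was 0.00817, 0.0222, 0.0210 and 0.0253 without a filter, and 0.0157, 0.0751, 0.0621 and 0.0653 with batch 3 alone. Among the brightest 30% it was 0.274, 0.181 and 0.204 at 10, 15 and 20 mM, and with an offset of 32 it was 0.125 at 15 mM.

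Of the gene lists at 5 mM, median centring called 2 higher, no filter 0, the block 2, the block with an estimated correlation 0 and an estimated correlation 0. Along the dose an estimated correlation called 0 higher and 0 lower, and median centring and the mean of all probe sets per gene each called 2 lower. With an array left out, 0 to 7 lists were higher and 0 to 5 lower at 5 mM, and 2 to 5 higher and 2 to 5 lower along the dose. List shifts at 5 mM that were called with opposite signs, depending on the array left out, were those of the integrated stress response (-0.29 to 0.37), endoplasmic reticulum chaperones (-0.32 to 0.27), glycolysis (-0.26 to 0.29), hypoxia targets (-0.52 to 0.40) and cytosolic ribosomal proteins (-0.10 to 0.17). The stress response stood at -0.28 without 0 mM of batch 1 and -0.29 without 5 mM of batch 3, and the hypoxia targets at 0.40 without 5 mM of batch 1 and 0.31 without 0 mM of batch 3. With an array left out, limma pooled the spread of the arrays that remained. At 5 mM these fits had no block, so leaving out 1 array of a pair left batch unbalanced between 0 and 5 mM. The shifts then hold differences between batches and cannot be read as changes of a NAM effect alone.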

Other observations

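Chosen only after the top genes were seen was the list of retinoic acid targets, so its counts and p-values are not independent evidence of its direction. The other lists here were fixed beforehand.

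Retinoic acid targets fell along the dose with a mean of -0.70, 9 of 11 falling (adjusted p 7.40e-04, and adjusted p = 0.0757 with an estimated correlation). ALDH1A2, which makes retinoic acid, had -1.17, the nuclear receptor gene NR2F1 -0.89, the homeobox gene MEIS2 -0.89, and the receptor genes RARA and RARB -3.50 and -0.92, while RET had 2.61. At 5 mM their mean was -0.35 and their median -0.29, with 8 of 12 lower and 4 higher. The member CYP26A1, described above, had -2.35 there, so 1 gene weighs heavily on that mean. The adjusted p values of this list cover only it and the HOX genes. No test of a shared regulator was run.

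Neuronal genes had a mean change of 0.31 along the dose (adjusted p 0.0868), with the neurofilament genes NEFL, NEFM and INA at 0.77, 0.77 and 0.97 and SNAP25 at 1.097. With all 9 arrays and the block the mean was 0.39 (adjusted p 0.0159), and the adjusted p was 0.420 with an estimated correlation. At 5 mM the mean was 0.17, called with the block (adjusted p 0.0177) and not with an estimated correlation beside it (0.940). In batch 1 the mean was 0.46, 0.52, 0.34 and 0.45 at 5, 10, 15 and 20 mM, and at 5 mM it was -0.32 and 0.04 in batches 2 and 3. Along the dose the list was also called without the filter on dim probe sets (mean 0.58, adjusted p 0.0204), with the mean of all probe sets per gene (0.35, adjusted p 0.0345), and without the 5 mM array (0.40, adjusted p 0.0462) or the 15 mM array (0.36, adjusted p 0.0460) of batch 1. At 5 mM it was called without the block when the 0 mM array of batch 3 was left out (0.31, adjusted p 0.00621).

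Cholesterol synthesis genes were not called along the dose (mean 0.19, adjusted p 0.0961), with IDI1 at 0.90, INSIG1 at 0.98, SQLE at 0.88 and HMGCS1 at 0.65, and FDPS at -0.61. Osmotic stress genes were not called either (mean 0.29, adjusted p 0.0954), with the kinase gene SGK1 at 1.46 and the inositol transporter gene SLC5A3 at 0.71. Along the dose the NAD synthesis list had a mean of 0.38 (adjusted p 0.346), the sirtuins 0.24 (0.502) and the PARP family -0.11 (0.644).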
